A study of Caenorhabditis elegans with 48 samples.

How the data were processed

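Values came from the deposited scanner files of 48 arrays, 45220 spots each, 1417 of them controls. Per the file headers, the gProcessedSignal, gMeanSignal and gBGMedianSignal columns hold intensity in scanner units (background-subtracted and detrended within the array for the first), and gIsWellAboveBG holds a flag of 0 or 1 rather than a measurement. The deposited value table holds a score, a z score of log2(gProcessedSignal) per array over all its spots, controls included. The file headers name Agilent Feature Extraction 9.5.1.1, and the authors' processing notes name Agilent Feature Extraction 9.1. Probe positions come from the array annotation on build ce6 (WS190).

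For each array, log2(gProcessedSignal) was taken relative to the array's 75th percentile over non-control spots. Spots marked by Feature Extraction as outliers were left out, which touched 434 of the genes tested, and spots of a probe were averaged. Of 43603 probes, 36696 matched 20239 genes by name or accession, and 6907 matched none and were left out. A probe was kept if it was well above background on at least 2 arrays of at least 1 of the 16 groups, which left 35841 probes and 17902 genes, each represented by its probe with the highest mean.

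The 46 arrays that the submitters kept entered 1 limma fit of 16 group means (lmFit and eBayes, 30 residual degrees of freedom, 2.078 prior degrees of freedom), with Benjamini-Hochberg adjusted p below 0.05 per comparison. Interactions were contrasts of that fit, and the joint tests over 3 compounds were moderated F tests. Gene lists were tested with camera at its preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. Of 44 lists, 43 had at least 5 measured genes and were tested, and the other had no measured gene. Where a group was well above background on none of its arrays, a fold is given as a bound against the background level. Simulated correlations and counts came from 100 draws of arrays without effects, made from the residuals of the fit. The comparisons, tests, lists, rule for naming genes and first set of alternatives were chosen before the data were examined.

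The rule for naming genes allowed the 8 highest and 8 lowest changes in each genotype and age comparison and the 4 highest and 4 lowest in each compound comparison and interaction, among genes past the threshold with a gene symbol of 3 or 4 letters and, except in interactions, with groups of arrays that did not overlap (10% of genes do so by chance with 3 arrays against 3). It also allowed up to 4 members of each list with the largest change past the threshold, and in any comparison atm-1, pink-1, pdr-1, dct-1, skn-1, sir-2.1, parp-1, pnc-1, nmrk-1, sod-3, gst-4, hsp-6, hsp-4, hsp-16.2, egl-1, cep-1, vit-2, daf-16 and hlh-30. From the genes and lists so allowed, those named were picked for length after the alternatives had been run. Genes and lists whose call was lost or turned under other settings were left out more often than others, so the numbers of named genes and lists that held under an alternative describe chosen ones and overstate how well genes and lists held in general.

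The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, no filter and a stricter filter (well above background on at least 0.5 of all arrays), the 2 excluded arrays added, the replicate number of the titles or of the descriptions as a block, the slide as a term (a random block for genotype and age, where each slide held 1 group compared), the authors' value table, only the groups of the comparison in the fit, each array left out in turn, a 2-fold limit, and the other probes of a gene. Alternatives chosen after seeing the data were leaving out the 2 dimmest arrays of the fit, the slide as a random block for the compounds (consensus correlation 0.077), and array weights. Replicate numbers did not pair the samples: in 0 of 16 comparisons did every pair of arrays with the same number correlate above 0.1 (r from -0.2 to 0.316 over 46 pairs).

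The code was tested on simulated data: of 200 genes given a log2 change of 1 in 1 comparison, 164 were called, all with the right sign. Of 34 members of a list shifted by 0.3, 17 were called, the list had an adjusted p of 1.99e-50, and none of 42 other lists passed. There were 11 calls among unchanged genes of that comparison and 1 over the 15 comparisons without a change. The tools were R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.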

Results

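RNA from whole Caenorhabditis elegans worms was measured on 48 single-colour Agilent arrays. The worms were the wild type strain N2 or the mutant atm-1, which carries a change in the gene of the worm homolog of the human ATM kinase, the enzyme lost in ataxia telangiectasia. Worms of each genotype were left untreated or were given 500 µM nicotinamide riboside (NR, a precursor of NAD+), 10 µM SRT1720 (named an inhibitor of SIRT1 in the labels, and known elsewhere as an activator of SIRT1) or 500 µM olaparib (an inhibitor of PARP enzymes). They were collected after 1 or 10 days of treatment from the L4 stage, which gave 16 groups of 3 arrays. The submitters left out 1 array of NR-treated atm-1 worms at day 1 and 1 array of olaparib-treated wild type worms at day 10, so those groups had 2 arrays and the other 14 had 3. Between 53.3% and 80% of the spots of an array were well above background (median 73.9%), and the 75th percentile of the signal ran from 1392 to 5458. The number of arrays per group limits the precision of every value.

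Gene changes are given as log2 fold changes ± SE from 1 limma fit over all 16 groups, with p adjusted over the 17902 genes tested. A gene list is said to move as a group where its camera test, adjusted over the 43 lists tested, passed 0.05. Each slide held 4 arrays of 1 genotype and day, and all 3 untreated arrays of a genotype and day shared a slide with NR replicate 1. With the slide as a term in the fit, an NR effect is that of NR replicate 1 against the 3 untreated arrays of its own slide. SRT1720 and olaparib arrays never shared a slide with untreated arrays, so their values with the slide as a term reach the untreated arrays through the groups that lie on 2 slides, and no value within a slide can be given for them.

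**Figure D1:**
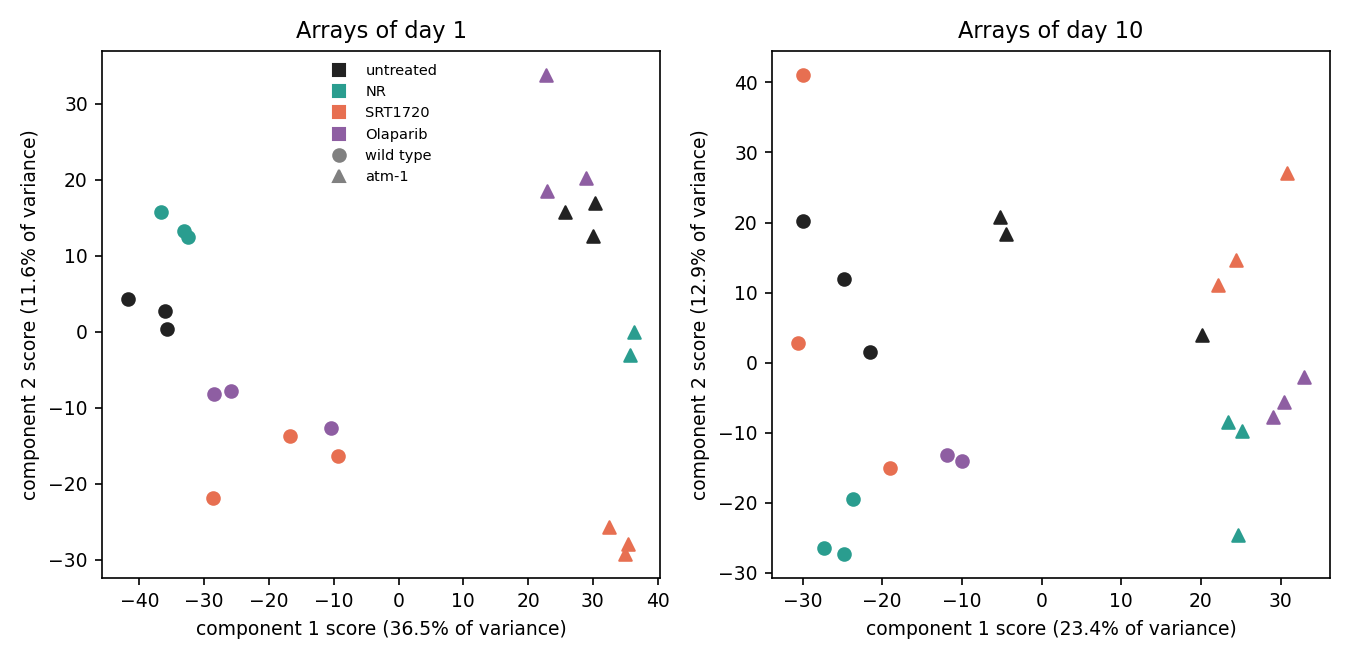
Scores of the arrays on the first 2 principal components, computed over the genes of the fit within day 1 (left) and within day 10 (right), with 1 point per array, colour for treatment and shape for genotype. Wild type and atm-1 arrays part along component 1 on both days, and at day 10 an untreated atm-1 array (score 20.2) lies beside the treated atm-1 arrays (22.1 to 33), away from the other 2 (-5.19 and -4.44).

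The first comparison asked how untreated atm-1 worms differed from the wild type at day 1 (3 arrays per genotype). Genes of the germ line and of genome upkeep were higher in atm-1 worms. Of the 72 measured DNA repair and replication genes, 57 rose, 0 fell and 15 did not pass (58 and 0 with p adjusted over the list alone), among them the nucleotide excision repair gene xpc-1 (log2 0.64 ± 0.14), the translesion polymerase rev-3 (log2 0.62 ± 0.12) and the recombination gene rad-54.L (log2 0.61 ± 0.12). For the cell cycle, of 53 genes 42 rose, 1 fell and 10 did not pass (43 and 1 over the list alone). For the germline list, of 36 genes 31 rose, 0 fell and 5 did not pass (33 and 0 over the list alone), with the Notch receptor glp-1 at 0.68 ± 0.10 and the RNA-binding protein gld-1 at 0.68 ± 0.12. In the DNA damage checkpoint and apoptosis list 16 rose, 1 fell and 11 did not pass (17 and 1 over the list alone), and the caspase ced-3 (log2 0.73 ± 0.13) and the p53 homolog cep-1 (log2 0.41 ± 0.06) were among the higher genes. Adjusted list p were 3.98e-18, 9.81e-15, 1.78e-12 and 1.81e-06 in that order, and the 4 calls held with an estimated correlation.

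Of the 41 mitophagy and autophagy genes, 16 rose, 1 fell and 24 did not pass (16 and 1 over the list alone, list adjusted p = 0.000138), with the autophagy gene epg-4 at 0.60 ± 0.09 and the mitophagy kinase pink-1 at 0.25 ± 0.08 (adjusted p = 0.0128). In the cytosolic heat shock list 12 rose, 2 fell and 12 did not pass (12 and 3 over the list alone, list adjusted p = 0.000244), with the small heat shock protein hsp-16.2 2.68-fold higher (log2 1.42 ± 0.13, adjusted p = 2.22e-10). Cuticle genes went the other way: 5 rose, 125 fell and 55 did not pass (5 and 129 over the list alone, list adjusted p = 1.78e-12), with the collagens col-41 (log2 -2.06 ± 0.15) and dpy-2 (log2 -1.96 ± 0.10) among the lowest. The sperm list had 2 higher, 58 lower and 6 not past the threshold (2 and 59 over the list alone, adjusted p = 3.74e-08, or 0.37 with an estimated correlation). Members included nspd-1 at -0.86 ± 0.12. Cytosolic ribosomal protein genes numbered 76 lower of 77 (0 and 76 over the list alone, adjusted p = 7.93e-09, or 0.504 with an estimated correlation), but the direction of that list turned to higher under normexp background correction with quantile normalization (adjusted p = 0.939) and the call ended under quantile normalization alone (0.812).

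The largest single differences lay outside these groups. The astacin metalloprotease nas-17 (K03B8.2, probe at chromosome V from 11400392 to 11400451 of build ce6) was at least 5.33-fold higher in atm-1 worms (adjusted p = 1.11e-06), since none of the 3 wild type arrays was well above background. The secreted proteins scl-9 and scl-7 were at least 7.3-fold and at least 4.22-fold higher on the same ground, and the C-type lectin clec-217 at least 4.57-fold. The lectin clec-219 was higher with signal in both genotypes (log2 3.07 ± 0.34, adjusted p = 1.12e-08). The alpha-tubulin gene tba-8 (ZK899.4, chromosome X from 9455498 to 9455620) was 6.62-fold lower (log2 -2.73 ± 0.17, adjusted p = 1.16e-13). The probe of atm-1 itself (Y48G1BL.2, chromosome I from 207892 to 207951) was well above background on all arrays and stood at 0.24 ± 0.16 in atm-1 worms (adjusted p = 0.203). It passed with equalised array distributions (log2 0.34 under normexp with quantile normalization, 0.41 under quantile normalization), array weights or only these 6 arrays in the fit (adjusted p from 0.0119 to 0.0355). The labels do not say which part of the gene the mutation alters, so this probe does not check the genotype. In all, 9193 of the 17902 genes passed the threshold, 3501 higher and 5692 lower, 985 by at least 2-fold. 22 of 43 lists moved as a group, 7 with an estimated correlation. The median of all genes was -0.106 here and 0.00325 or 0.00424 with the array distributions made equal (normexp with quantile, or quantile alone), where 3918 genes were higher and 4171 lower, or 4002 and 3857. In the authors' value table the majority turned too (3493 higher and 2794 lower). The untreated arrays of each genotype lay on 1 slide, so the slide as a random block (8342 genes) cannot part slide from genotype. Genotype differences on the other 2 pairs of slides at day 1 correlated with those of untreated worms at 0.672 and 0.635 across genes.

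At day 10 the same comparison of untreated worms (3 arrays per genotype) gave fewer genes. The lectin clec-219 was again higher in atm-1 worms (log2 2.17 ± 0.34, adjusted p = 1.82e-05), as was clec-208 (log2 2.16 ± 0.36), while sysm-1, a gene of intestinal immune responses, was 4.02-fold lower (log2 -2.01 ± 0.18, adjusted p = 1.11e-09). Sperm genes were higher at this age: of 66, 31 rose, 1 fell and 34 did not pass (36 and 2 over the list alone), with the major sperm protein msp-37 at 0.69 ± 0.12 (list adjusted p = 1.14e-09, or 0.752 with an estimated correlation). Of the 47 genes of fatty acid desaturation, elongation and lipases, 3 rose, 16 fell and 28 did not pass (4 and 20 over the list alone), with the lipases lips-11 at -1.38 ± 0.19 and lipl-2 at -1.01 ± 0.09 (list adjusted p = 0.00699, or 0.752 with an estimated correlation). hsp-16.2, higher at day 1, was lower at day 10 (log2 -0.60 ± 0.13, adjusted p = 0.00083), and the atm-1 probe was at -0.23 ± 0.16 (adjusted p = 0.308). In all, 4374 genes passed the threshold, 1933 higher and 2441 lower, 317 by at least 2-fold (160 higher, 157 lower). 8 of 43 lists moved as a group, 0 with an estimated correlation. The count was 1695 with only these 6 arrays in the fit and 3459 with the slide as a random block, limited as at day 1.

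The change from day 1 to day 10 in untreated wild type worms (3 arrays per day) took in most of the genes. Cuticle genes fell: 20 rose, 151 fell and 14 did not pass (20 and 152 over the list alone), with the collagen col-81 (F38A3.1, chromosome II from 11012847 to 11012906) at -10.66 ± 0.27. In the muscle list 3 rose, 35 fell and 9 did not pass (4 and 36 over the list alone), with the troponin T gene tnt-2 at -5.24 ± 0.09. For one-carbon and amino acid metabolism 2 rose, 27 fell and 3 did not pass (2 and 27 over the list alone), with the acyl-CoA dehydrogenase acdh-1 at -7.34 ± 0.21 and the S-adenosylmethionine synthetase sams-1 at -2.81 ± 0.15. These 3 lists had adjusted p = 2.19e-27, 6.44e-08 and 7.12e-07 and held with an estimated correlation. Sperm genes also fell (63 of 66, none rose, 0 and 63 over the list alone), with nspd-3 at -4.64 ± 0.14 and the major sperm protein msp-31 at -4.3 ± 0.20 (adjusted p = 3.47e-21, or 0.131 with an estimated correlation). Mitochondrial genes were lower: of 57 genes 3 rose, 43 fell and 11 did not pass in oxidative phosphorylation (3 and 43 over the list alone, cytochrome c gene cyc-2.2 -3.9 ± 0.11) and 2 rose, 25 fell and 3 did not pass in the TCA and glyoxylate cycles (2 and 25 over the list alone, malate dehydrogenase mdh-2 -2.09 ± 0.10). Their adjusted list p were 5.6e-06 and 6.78e-05, and the calls were lost with an estimated correlation (adjusted p = 0.159 and 0.121).

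Other genes rose with age in the wild type. The mitophagy and autophagy list had 31 higher, 2 lower and 8 not past the threshold of 41 (31 and 2 over the list alone, adjusted p = 0.00097, held with an estimated correlation), with the p62 homolog sqst-1 at 2.86 ± 0.09 and atg-16.2 at 1.88 ± 0.06, while pink-1 fell (log2 -0.69 ± 0.08, adjusted p = 5.38e-09). In the cytosolic heat shock list 17 rose, 2 fell and 7 did not pass (17 and 2 over the list alone), with hsp-16.2 at 6.35 ± 0.13 and hsp-70 at 5.7 ± 0.60 (list adjusted p = 0.0091, or 0.16 with an estimated correlation). The iron store ferritin ftn-1 rose 32.4-fold (log2 5.02 ± 0.08, adjusted p = 6.86e-32), the caenacin cnc-6 710-fold (log2 9.47 ± 0.24) and the saposin-like spp-20 361-fold (log2 8.49 ± 0.24). In all, 13993 genes passed the threshold, 8052 higher and 5941 lower, 7306 by at least 2-fold. 19 of 43 lists moved as a group, 4 with an estimated correlation.

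In untreated atm-1 worms the change from day 1 to day 10 (3 arrays per day) resembled that of the wild type, with r = 0.945 across genes, which are not independent replicates. Cuticle (22 rose, 145 fell and 18 did not pass, 22 and 146 over the list alone, adjusted p = 2.57e-23), muscle (3 rose, 37 fell and 7 did not pass, 3 and 37 over the list alone, adjusted p = 4.01e-08) and one-carbon genes (3 rose, 27 fell and 2 did not pass, 3 and 27 over the list alone, adjusted p = 5.62e-06) fell, and these 3 calls held with an estimated correlation. Examples were col-81 at -9.59 ± 0.27, tnt-2 at -4.83 ± 0.09 and acdh-1 at -8.42 ± 0.21. Sperm genes numbered 3 higher, 59 lower and 4 not past the threshold (3 and 59 over the list alone, adjusted p = 6.56e-16, or 0.211 with an estimated correlation). Members included nspd-3 at -3.34 ± 0.14. For DNA repair and replication 16 rose, 45 fell and 11 did not pass (16 and 46 over the list alone, adjusted p = 0.00354, or 0.419 with an estimated correlation), with rad-54.L at -1.47 ± 0.12, and cep-1 fell too (log2 -0.83 ± 0.06).

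Of the 30 genes of NAD metabolism, sirtuins and PARPs, 7 rose, 16 fell and 7 did not pass in ageing atm-1 worms (7 and 16 over the list alone), the kynurenine pathway gene haao-1 at -2.4 ± 0.09 and the poly(ADP-ribose) glycohydrolase parg-2 at 3.14 ± 0.07. The wild type gave similar numbers (7 rose, 14 fell and 9 did not pass), though the list did not pass there (adjusted p = 0.119). In atm-1 worms the list was near the threshold (adjusted p = 0.0439, or 0.364 with an estimated correlation). Its call also ended under both equalised array distributions, a stricter filter, a replicate block by description number, a fit of these 6 arrays, or without untreated day 1 replicate 3 (adjusted p from 0.0518 to 0.109). In the mitophagy and autophagy list 24 rose, 5 fell and 12 did not pass (24 and 5 over the list alone, adjusted p = 0.0278, or 0.141 with an estimated correlation). Members included sqst-1 at 3.22 ± 0.09 and pink-1 at -0.99 ± 0.08. hsp-16.2 rose 20-fold (log2 4.32 ± 0.13), ftn-1 43.2-fold (log2 5.43 ± 0.08), cnc-6 477-fold (log2 8.9 ± 0.24) and spp-20 394-fold (log2 8.62 ± 0.24). In all, 14168 genes passed the threshold, 7901 higher and 6267 lower, 7184 by at least 2-fold. 24 of 43 lists moved as a group, 3 with an estimated correlation. The median of all genes was 0.145 in this comparison and 0.0356 or 0.0485 with equalised distributions.

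The age changes (atm-1 minus wild type) were compared as an interaction. Cuticle genes had 107 higher, 7 lower and 71 not past the threshold (109 and 9 over the list alone, adjusted p = 1.15e-14). They included dpy-9 (log2 2.24 ± 0.13) and col-10 (log2 2.38 ± 0.36). tba-8 also had a positive interaction (log2 2.74 ± 0.25, adjusted p = 6e-10). Negative interactions gathered in DNA repair and replication (47 of 72, 1 and 50 over the list alone, adjusted p = 4.82e-15), DNA damage and apoptosis (17 of 28, 0 and 17 over the list alone, adjusted p = 1.33e-07) and the cell cycle (23 of 53, 1 and 30 over the list alone, adjusted p = 4.65e-09). Those 4 calls held with an estimated correlation. The mitophagy and autophagy list (10 lower and 2 higher of 41, 1 and 10 over the list alone, adjusted p = 0.00395) held too. It failed under normexp (adjusted p = 0.147). These 5 lists passed for genotype at day 1 but not at day 10 (adjusted p from 0.0583 to 0.785). Their terms mostly restate that day 1 difference, which slide and brightness may affect. Sperm genes had 59 positive and 2 negative terms (62 and 2 over the list alone, adjusted p = 1.79e-15, or 0.19 with an estimated correlation). hsp-16.2 rose less in atm-1 worms (interaction log2 -2.03 ± 0.18, adjusted p = 6.19e-10), the lectin clec-183 was at -3.15 ± 0.33 and dct-8 at -2.47 ± 0.18. pink-1 did not pass (log2 -0.29 ± 0.12, adjusted p = 0.0548). It did with either replicate block, without the dim arrays, or without some single untreated day 10 arrays (adjusted p from 0.0134 to 0.0489). In all, 6381 genes passed the threshold, 3703 higher and 2678 lower, and the majority turned under quantile normalization (2788 and 2971) and in the authors' value table (1924 and 2212).

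**Figure D2:**
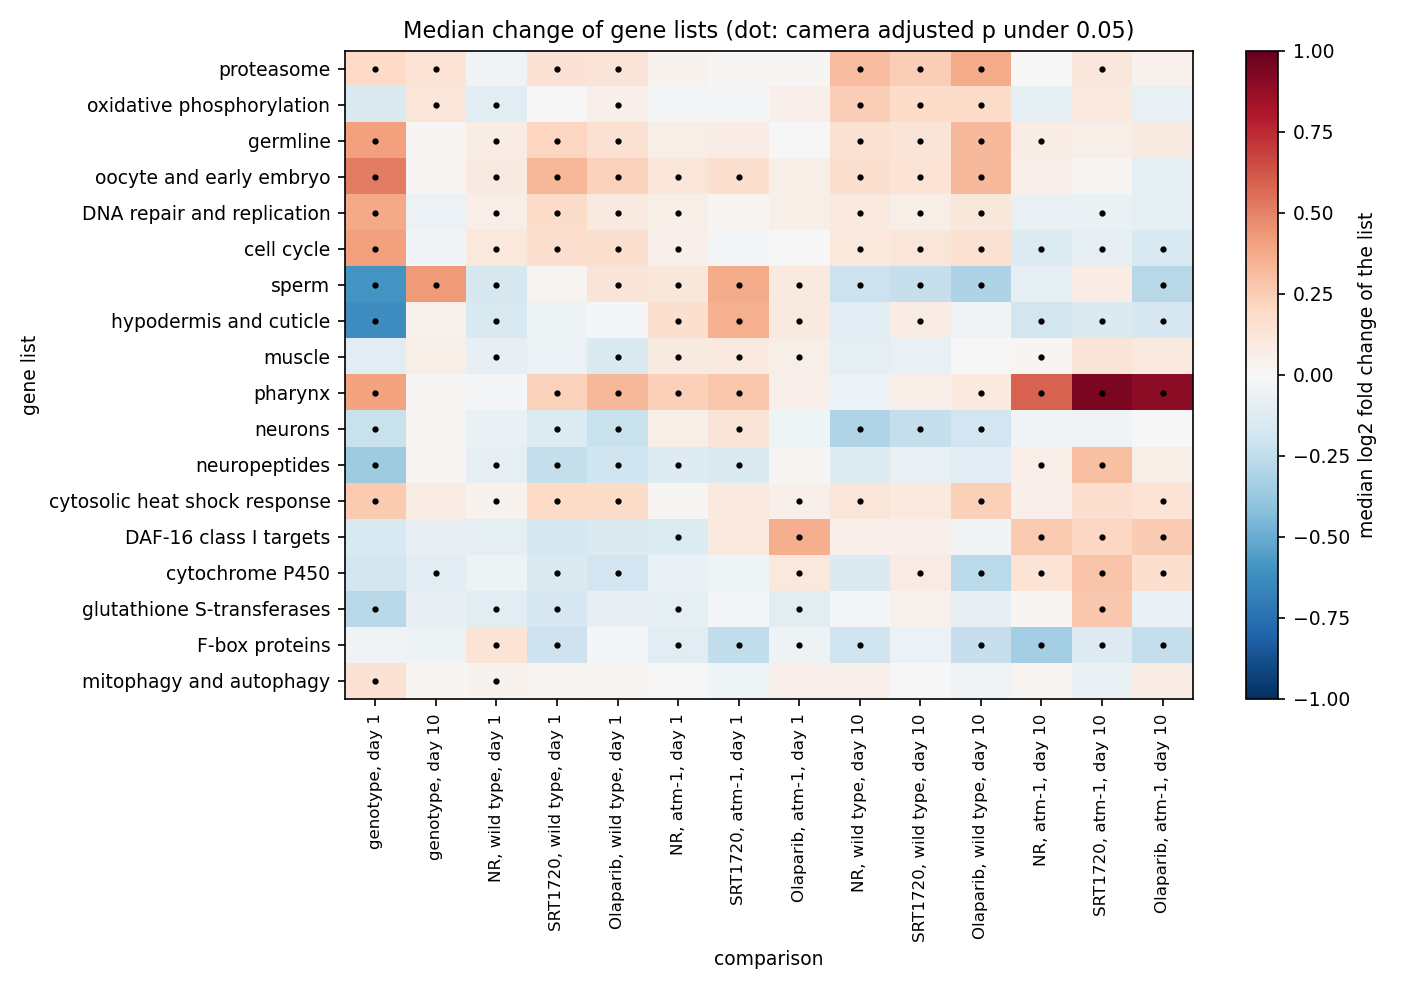
Median log2 fold change of 18 of the gene lists (vertical axis) in the genotype and compound comparisons (horizontal axis), on a colour scale from -1 to 1 that levels off at its ends, with a dot where the camera test passed an adjusted p of 0.05. Proteasome genes had positive medians with each compound in the wild type at day 10 (0.311, 0.245 and 0.369), and pharynx genes in atm-1 worms at day 10 (0.586, 0.942 and 0.897).

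**Figure D3:**
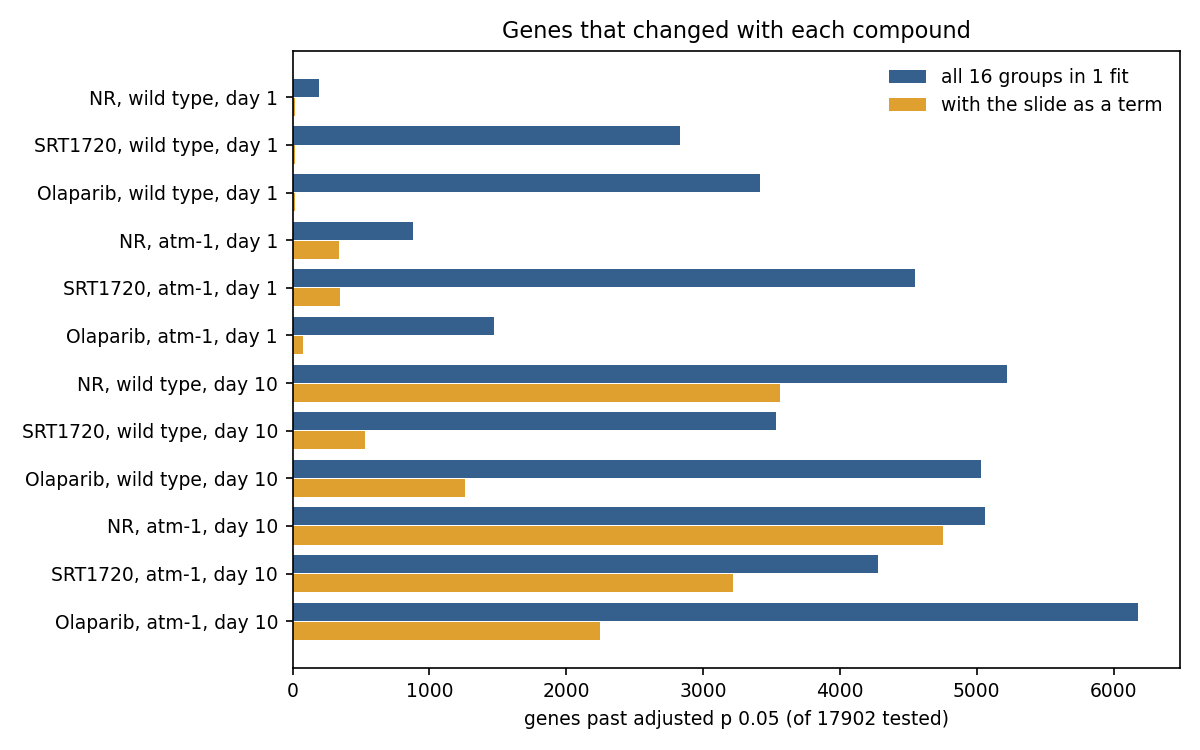
Number of genes past an adjusted p of 0.05 (horizontal axis) in each of the 12 compound comparisons (vertical axis), from the fit of all groups and with the slide as a further term. With the slide as a term the counts ran from 14 (SRT1720, wild type, day 1) to 4754 (NR, atm-1, day 10).

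The compound comparisons asked what each treatment did to gene expression within a genotype and day. NR in wild type worms at day 1 (3 arrays against 3) changed few genes. hsp-16.2 rose 1.83-fold (log2 0.87 ± 0.13, adjusted p = 0.00035), the F-box gene fbxb-78 rose (log2 0.80 ± 0.14, adjusted p = 0.0018), the lysosomal lipase lipl-1 fell (log2 -0.68 ± 0.10, adjusted p = 0.000347) and ftn-1 fell (log2 -0.43 ± 0.08, adjusted p = 0.00531). In the F-box list of 345 genes 19 rose, 0 fell and 326 did not pass (57 and 1 over the list alone, list adjusted p = 2.02e-13, or 0.373 with an estimated correlation). The heat shock list had 4 higher, 0 lower and 22 not past the threshold (4 and 0 over the list alone, adjusted p = 0.00257, or 0.246 with an estimated correlation), and its call ended without untreated replicate 3 (adjusted p = 0.0569, the highest over single arrays left out). No gene of the cell cycle list passed on its own, also over the list alone, while the list's median was 0.109 (adjusted p = 1.32e-06, or 0.246 with an estimated correlation). In all, 196 genes passed the threshold, 84 of them lower and the others higher. The majority turned with array weights (1938 higher and 2437 lower), without NR replicate 1 (37 and 59) and without untreated replicate 1 (74 and 79). 19 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 12 passed in the same direction with the slide as a term. With the slide as a term 20 genes passed. The call held for hsp-16.2 at 1.0, lipl-1 at -0.62 and fbxb-78 at 0.97, and was lost for ftn-1 at -0.39. With only these 6 arrays in the fit the calls of fbxb-78 and ftn-1 were lost, and that of ftn-1 also in the authors' value table. With the slide as a term the 3 lists above had adjusted p of 3.84e-18, 0.00696 and 0.00696. The count was 65 without untreated replicate 2, and 96 to 110 without any one of NR replicates 1, 2 and 3.

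SRT1720 in wild type worms at day 1 (3 arrays against 3) raised the cytochrome P450 gene cyp-35B3 (K07C6.2, chromosome V from 3946968 to 3947027) 2.88-fold (log2 1.53 ± 0.10, adjusted p = 1.88e-12), cror-1 2.74-fold (log2 1.45 ± 0.16, adjusted p = 3.6e-07) and hsp-16.2 2.04-fold (log2 1.03 ± 0.13, adjusted p = 5.14e-06). Oocyte and early embryo genes rose together (of 33 genes 23 rose, 0 fell and 10 did not pass, 27 and 0 over the list alone, oma-2 0.53 ± 0.11), as did germline genes (of 36 genes 15 rose, 0 fell and 21 did not pass, 21 and 0 over the list alone) and DNA repair genes (of 72 genes 18 rose, 0 fell and 54 did not pass, 22 and 0 over the list alone, with the helicase gene fncm-1 at 0.33 ± 0.06). The heat shock list had 7 higher, 3 lower and 16 not past the threshold (10 and 3 over the list alone). List p were 9.2e-16, 1.11e-11, 3.59e-13 and 8.39e-05, and the 4 calls held with an estimated correlation. The desaturase fat-5 fell (log2 -0.94 ± 0.07). The ubiquitin-like ubl-5, a gene of the mitochondrial unfolded protein response, fell (log2 -0.77 ± 0.13, adjusted p = 0.000234). In all, 2832 genes passed the threshold, 898 higher and 1934 lower. 23 of 43 lists moved as a group, 5 with an estimated correlation. Of those lists, 15 passed in the same direction with the slide as a term, the 4 above among them (adjusted p from 2.28e-08 to 0.0002). Only 14 genes passed with the slide as a term, where the majority turned (9 higher and 5 lower). They included cyp-35B3 (1.89), cror-1 (1.51), hsp-16.2 (1.36) and fat-5 (-0.90). The call was lost for oma-2 (0.30), fncm-1 (0.23) and ubl-5 (-0.51). The count was 1187 without untreated replicate 3 and 1211 without SRT1720 replicate 3.

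Olaparib in wild type worms at day 1 (3 arrays against 3) raised the small heat shock genes hsp-16.2 5.85-fold (log2 2.55 ± 0.13, adjusted p = 2.91e-15), hsp-16.41 3.08-fold (log2 1.62 ± 0.14, adjusted p = 1.11e-09) and hsp-16.1 2.95-fold (log2 1.56 ± 0.10, adjusted p = 6.19e-12). In the cytosolic heat shock list of 26 genes 8 rose, 2 fell and 16 did not pass (10 and 2 over the list alone, adjusted p = 2.61e-06, held with an estimated correlation). ABC transporters went down (of 38 genes 0 rose, 18 fell and 20 did not pass, 0 and 19 over the list alone, adjusted p = 4.85e-07, or 0.0638 with an estimated correlation). Members included the P-glycoprotein gene pgp-8 at -0.75 ± 0.06 and mrp-2 at -0.71 ± 0.11. The neuron list had 0 higher, 24 lower and 38 not past the threshold (0 and 27 over the list alone, adjusted p = 2.48e-07, or 0.0638 with an estimated correlation). Members included the touch channel gene mec-4 at -0.75 ± 0.13. The body wall myosin myo-3 fell (log2 -0.71 ± 0.09). In all, 3419 genes passed the threshold, 1277 higher and 2142 lower. 24 of 43 lists moved as a group, 1 with an estimated correlation. Of those lists, 10 passed in the same direction with the slide as a term, the 3 above among them (adjusted p from 2.18e-08 to 0.000325). Only 17 genes passed with the slide as a term, where the majority turned (9 higher and 8 lower). They included hsp-16.2 (3.16), hsp-16.41 (2.37), hsp-16.1 (1.86) and pgp-8 (-0.74). The call was lost for mrp-2 (-0.52), mec-4 (-0.83) and myo-3 (-0.86). The count was 1898 without untreated replicate 3, 2167 without olaparib replicate 1 and 1118 with only these 6 arrays in the fit.

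NR in atm-1 worms at day 1 (2 arrays against 3) lowered part of the genes that embryos switch on: of the 30 measured, 0 rose, 9 fell and 21 did not pass (0 and 11 over the list alone, list adjusted p = 3.49e-09, or 0.0604 with an estimated correlation). The endoderm GATA factor end-1 (log2 -0.68 ± 0.13, adjusted p = 0.00152) and the homeobox gene ceh-51 (log2 -0.74 ± 0.12, adjusted p = 0.000413) were among them. In the ABC transporter list of 38 genes 3 rose, 0 fell and 35 did not pass (4 and 0 over the list alone, adjusted p = 5.3e-06, or 0.0974 with an estimated correlation). Members included pgp-8 at 0.58 ± 0.06. The noncoding RNA gene rncs-1 was 3.73-fold lower (log2 -1.9 ± 0.36, adjusted p = 0.00158), the small heat shock protein hsp-12.3 was at -0.70 ± 0.09 and the saposin-like spp-2 at -0.76 ± 0.11. In all, 883 genes passed the threshold, 262 higher and 621 lower, or 404 higher and 528 lower of 932 under normexp with quantile normalization. 17 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 14 passed in the same direction with the slide as a term, both lists above among them (adjusted p = 2.03e-07 and 0.000468). With the slide as a term 339 genes passed, and all 6 named kept their call (end-1 -0.67, ceh-51 -0.78, pgp-8 0.62, rncs-1 -1.99, hsp-12.3 -0.75 and spp-2 -0.82). The end-1 call was lost in the authors' value table. The count was 194 or 226 without NR replicate 1 or 2, 410 or 387 without untreated replicate 2 or 3, and 1949 with the arrays that the submitters left out.

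SRT1720 in atm-1 worms at day 1 (3 arrays against 3) raised the glycerol-3-phosphate dehydrogenase gpdh-1 (F47G4.3, chromosome I from 14077965 to 14078024) 6.16-fold (log2 2.62 ± 0.07, adjusted p = 2.02e-24) and the myo-inositol transporter hmit-1.1 6.16-fold (log2 2.62 ± 0.13, adjusted p = 1.56e-16). cyts-1 rose 6.45-fold (log2 2.69 ± 0.09) and dct-8 fell 4.77-fold (log2 -2.25 ± 0.12). The antimicrobial peptide gene nlp-29 was at 1.32 ± 0.15. Cuticle genes had 78 higher, 25 lower and 82 not past the threshold (89 and 29 over the list alone, adjusted p = 4.25e-08, or 0.364 with an estimated correlation). Members included col-66 at 1.33 ± 0.30. For sperm genes 35 rose, 0 fell and 31 did not pass (39 and 0 over the list alone, adjusted p = 4.62e-11, or 0.627 with an estimated correlation). In the endoplasmic reticulum stress list 9 rose, 0 fell and 23 did not pass (9 and 0 over the list alone, adjusted p = 0.000641, or 0.086 with an estimated correlation). Members included abu-10 at 1.38 ± 0.18. In all, 4552 genes passed the threshold, 2282 higher and 2270 lower, and under several alternatives lower genes were the more numerous (1826 and 2270 under quantile normalization). 13 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 7 passed in the same direction with the slide as a term, the 3 above among them (adjusted p from 2.02e-06 to 0.00175). 347 genes passed with the slide as a term. They included gpdh-1 (2.5), hmit-1.1 (2.68), cyts-1 (2.77), dct-8 (-2.17), nlp-29 (1.29) and abu-10 (1.55). The call was lost for col-66 (1.08).

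Olaparib in atm-1 worms at day 1 (3 arrays against 3) raised the cytochrome P450 genes cyp-37B1 (F28G4.1, chromosome V from 16280460 to 16280519) 6.32-fold (log2 2.66 ± 0.07, adjusted p = 7.46e-25) and cyp-34A9 2.96-fold (log2 1.57 ± 0.09, adjusted p = 2.08e-14). In the cytochrome P450 list of 74 genes 18 rose, 3 fell and 53 did not pass (21 and 5 over the list alone, adjusted p = 3.39e-05, or 0.356 with an estimated correlation). Genes induced by the FOXO factor DAF-16 rose together: of 28 genes 14 rose, 1 fell and 13 did not pass (15 and 1 over the list alone, adjusted p = 2.4e-11, or 0.206 with an estimated correlation). Members included the metallothionein mtl-1 at 2.1 ± 0.13 and dod-3 at 1.89 ± 0.12. dct-8 (log2 2.4 ± 0.12) rose, as did the fatty acid oxidation genes acs-2 (log2 1.81 ± 0.12), an acyl-CoA synthetase, and cpt-3 (log2 1.34 ± 0.09). hsp-16.2 rose too (log2 0.84 ± 0.13, adjusted p = 2.81e-05). In all, 1470 genes passed the threshold, 777 higher and 693 lower. The majority turned under normexp with quantile normalization (597 and 646), quantile normalization alone (593 and 660) and in the authors' value table (293 and 468). 13 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 6 passed in the same direction with the slide as a term, both lists above among them (adjusted p from 2.54e-10 to 0.00304). With the slide as a term 79 genes passed, 61 higher and 18 lower. They included cyp-37B1 (2.77), cyp-34A9 (1.5), mtl-1 (2.37), dod-3 (2.25), dct-8 (2.78), acs-2 (2.03) and cpt-3 (1.51). The call was lost for hsp-16.2 (0.77). The count was 872 without olaparib replicate 3, a dim array on which 64.6% of spots were well above background.

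Whether the compounds acted differently in both genotypes at day 1 was tested by interactions (effect in atm-1 worms minus effect in the wild type). For NR acs-2 (log2 -1.4 ± 0.17, adjusted p = 6.69e-05), rncs-1 (log2 -3.04 ± 0.49, adjusted p = 0.000959) and fbxb-4 (log2 -1.1 ± 0.20, adjusted p = 0.00331) had negative terms. So did 38 of 345 F-box genes (3 and 74 over the list alone, adjusted p = 2.24e-15, or 0.303 with an estimated correlation) and 6 of 30 zygotically expressed genes (0 and 13 over the list alone, adjusted p = 1.63e-11, held with an estimated correlation), a list lower with each compound in atm-1 worms. In all, 412 genes passed the threshold, 158 higher and 254 lower, and with the slide as a term the 3 named genes were at -1.4, -3.62 and -1.26 and still passed, while fbxb-4 lost its call in the authors' value table. For SRT1720 2239 genes passed, with cuticle genes mostly positive where they passed (59 positive, 11 negative and 115 not past the threshold, 67 and 16 over the list alone, adjusted p = 3.23e-08, or 0.207 with an estimated correlation). For olaparib 3150 genes passed, among them cyp-37B1 (log2 2.65 ± 0.09, adjusted p = 4.01e-20) and 25 positive and 2 negative of 74 cytochrome P450 genes (28 and 3 over the list alone, adjusted p = 2.85e-06, or 0.173 with an estimated correlation). fipr-24 (log2 2.95 ± 0.23) and fipr-26 (log2 2.68 ± 0.30) were positive and hsp-16.2 was negative (log2 -1.71 ± 0.18, adjusted p = 3.16e-08), and with the slide as a term fipr-26 alone of these 4 lost its call (2.37, against 2.55, 2.95 and -2.39). A joint test over the 3 compounds gave 5063 genes, and 1136 with the slide as a term.

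**Figure D4:**
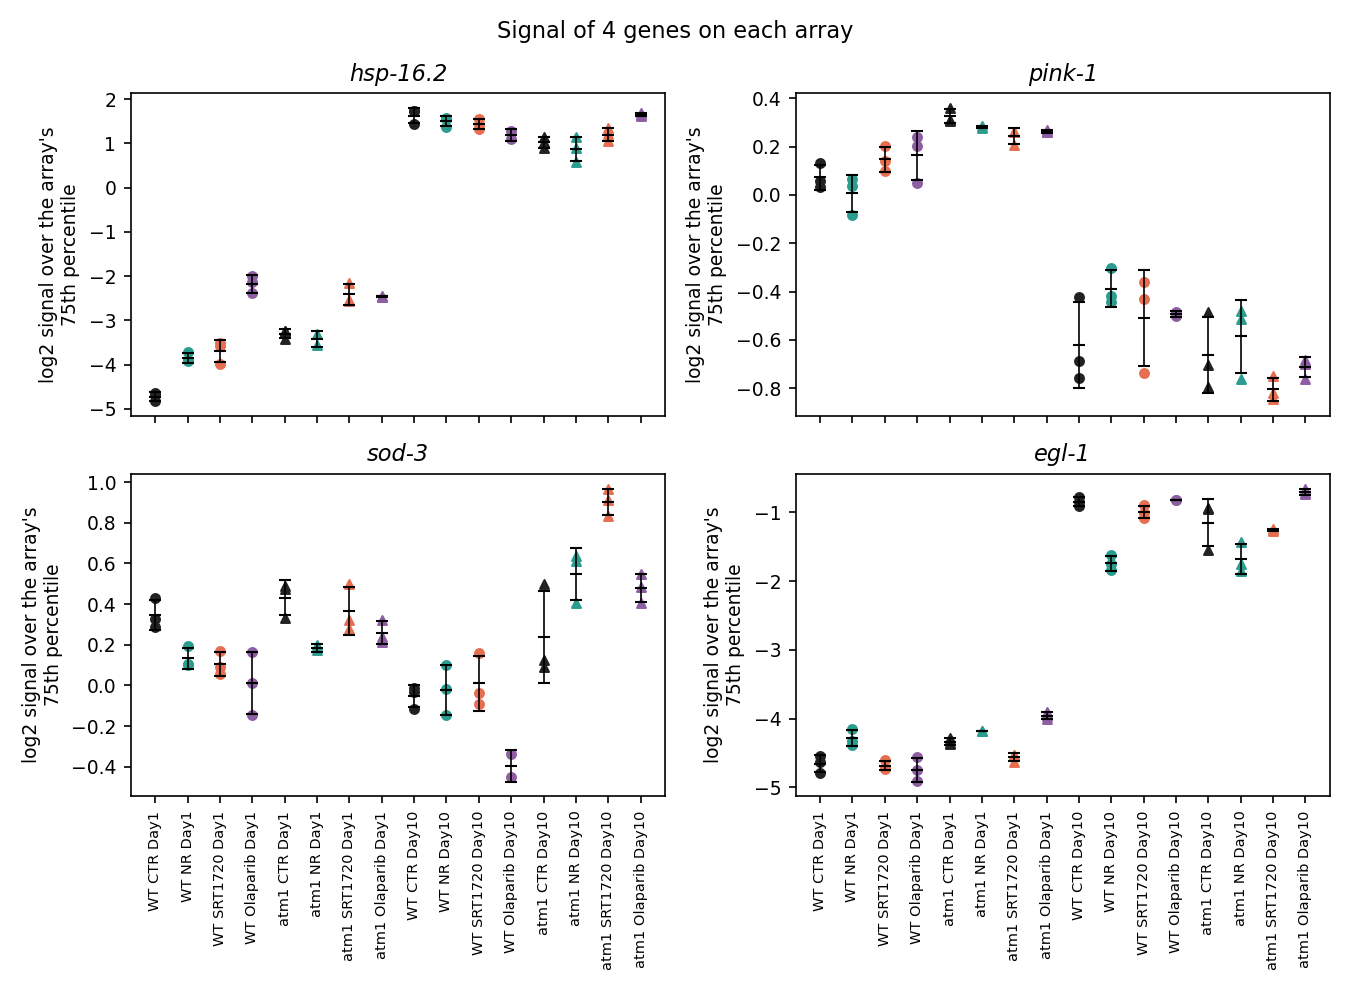
Log2 signal over the array's 75th percentile (vertical axes) of hsp-16.2, pink-1, sod-3 and egl-1 on each array of the 16 groups (horizontal axis), with 1 point per array, circles for wild type and triangles for atm-1 worms, colour for treatment, and bars for the mean ± SD. The pink-1 values lay higher at day 1 than at day 10 in every group, and those of hsp-16.2 and egl-1 lay lower at day 1.

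NR in wild type worms at day 10 (3 arrays against 3) raised pud-1.1 (F15E11.13, chromosome V from 2330868 to 2330927) 4.11-fold (log2 2.04 ± 0.13, adjusted p = 7.73e-13) and pud-4 3.06-fold (log2 1.61 ± 0.15), genes of proteins that rise in daf-2 mutants, and lowered sysm-1 (log2 -1.62 ± 0.18). Proteasome genes rose together: of 34 genes 24 rose, 0 fell and 10 did not pass (26 and 0 over the list alone), with the subunits rpn-5 at 0.68 ± 0.09 and pbs-1 at 0.53 ± 0.08. Of the 57 genes of oxidative phosphorylation, 31 rose, 0 fell and 26 did not pass (32 and 2 over the list alone), with the ATP synthase gene asb-1 at 0.47 ± 0.07, and of the 30 genes of the TCA and glyoxylate cycles, 14 rose, 0 fell and 16 did not pass (16 and 0 over the list alone), with the isocitrate dehydrogenase idhb-1 at 0.41 ± 0.07. The adjusted p of these lists were 9.93e-14, 6.03e-10 and 2.39e-06, and each was lost at adjusted p = 0.0618 with an estimated correlation. The neuron list had 1 higher, 24 lower and 37 not past the threshold (1 and 29 over the list alone, adjusted p = 2.25e-05, or 0.171 with an estimated correlation). Members included the cilium dynein che-3 at -0.85 ± 0.15. The BH3-only death gene egl-1 fell (log2 -0.89 ± 0.11, adjusted p = 3.49e-07), acdh-1 rose (log2 1.09 ± 0.21), and pink-1 was just past the threshold (log2 0.23 ± 0.08, adjusted p = 0.0348).

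In all, 5221 genes passed the threshold, 2069 higher and 3152 lower, against 940 and 919 in the authors' value table. 18 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 12 passed in the same direction with the slide as a term, the proteasome, oxidative phosphorylation, TCA and neuron lists among them (adjusted p from 7.3e-11 to 0.000311). The count was 3559 with the slide as a term. The call held for pud-1.1 at 2.21, pud-4 at 1.74, sysm-1 at -1.58, rpn-5 at 0.79, pbs-1 at 0.59, asb-1 at 0.55, idhb-1 at 0.45, che-3 at -1.11, egl-1 at -0.91 and acdh-1 at 1.05. The asb-1 call was lost in the authors' value table. The pink-1 call ended there, with only these 6 arrays in the fit, with the slide as a random block (0.22) or as a term (0.20), and without untreated replicate 1 (0.20) or 3 (0.17) or NR replicate 1 (0.25) or 2 (0.19).

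SRT1720 in wild type worms at day 10 (3 arrays against 3) raised the cytochrome P450 genes cyp-35B2 4.61-fold (log2 2.21 ± 0.10, adjusted p = 1.16e-16) and cyp-35B3 3.83-fold (log2 1.94 ± 0.10, adjusted p = 8.69e-16), as well as the UDP-glucuronosyltransferase ugt-8 1.81-fold (log2 0.86 ± 0.10) and the P-glycoprotein pgp-13 1.85-fold (log2 0.88 ± 0.11). The cytochrome P450 list had 14 higher, 8 lower and 52 not past the threshold of 74 (14 and 8 over the list alone, adjusted p = 0.00527, or 0.444 with an estimated correlation). Proteasome genes rose (of 34 genes 21 rose, 0 fell and 13 did not pass, 25 and 1 over the list alone, rpn-5 0.53 ± 0.09), as did those of oxidative phosphorylation (19 rose, 1 fell and 37 did not pass, 24 and 3 over the list alone) and of the TCA and glyoxylate cycles (11 rose, 0 fell and 19 did not pass, 13 and 0 over the list alone). Their adjusted list p were 1.29e-10, 1.97e-08 and 1.58e-06, and each was lost at adjusted p = 0.115 with an estimated correlation. The ribonucleotide reductase rnr-1 rose (log2 0.51 ± 0.06, adjusted p = 8.06e-07) and the small heat shock protein hsp-12.6 fell (log2 -0.94 ± 0.08, adjusted p = 4.78e-09). In all, 3535 genes passed the threshold, 1416 higher and 2119 lower, and the majority turned with the slide as a term (318 and 214) and with only these 6 arrays in the fit (25 and 10). 18 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 11 passed in the same direction with the slide as a term, the 4 above among them (adjusted p from 1.33e-07 to 0.00283), and 1 list passed in the opposite direction. The count was 532 with the slide as a term. The call held for cyp-35B2 at 2.48, cyp-35B3 at 1.97, ugt-8 at 0.78, pgp-13 at 1.15, rpn-5 at 0.64, rnr-1 at 0.47 and hsp-12.6 at -1.09. The count was 35 with only these 6 arrays in the fit, where ugt-8, pgp-13, rpn-5 and rnr-1 lost their calls, 1677 without SRT1720 replicate 3 (a dim array, 53.3% of spots well above background), and 1923 or 2184 without untreated replicate 1 or 3.

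Olaparib in wild type worms at day 10 (2 arrays against 3) raised the mitochondrial chaperones hsp-60 2.13-fold (log2 1.09 ± 0.22, adjusted p = 0.000424) and hsp-6 1.79-fold (log2 0.84 ± 0.14, adjusted p = 4.97e-05), and parp-1, which encodes a worm PARP enzyme, 1.55-fold (log2 0.63 ± 0.16, adjusted p = 0.00331). Proteasome genes rose (of 34 genes 25 rose, 1 fell and 8 did not pass, 26 and 1 over the list alone, adjusted p = 4.1e-16), with rpn-1 at 0.87 ± 0.15 and pas-6 at 0.62 ± 0.09, and TCA and glyoxylate cycle genes rose (of 30 genes 15 rose, 0 fell and 15 did not pass, 15 and 0 over the list alone, adjusted p = 5.5e-09), with mdh-2 at 0.81 ± 0.11. Both calls held with an estimated correlation. The recombinase rad-51 rose (log2 0.72 ± 0.11), and hsp-12.6 (log2 -1.28 ± 0.09), che-3 (log2 -1.18 ± 0.16) and the ABC transporter abt-2 (log2 -0.88 ± 0.12) fell. In all, 5031 genes passed the threshold, 1836 higher and 3195 lower. 23 of 43 lists moved as a group, 2 with an estimated correlation. Of those lists, 10 passed in the same direction with the slide as a term, both lists above among them (adjusted p from 7.54e-08 to 0.0038), and 1 list passed in the opposite direction. 1257 genes passed with the slide as a term. They included hsp-12.6 (-1.51) and che-3 (-1.21). The call was lost for hsp-60 (0.47), hsp-6 (0.37), parp-1 (0.17), rpn-1 (1.0), pas-6 (0.43), mdh-2 (0.51), rad-51 (0.58) and abt-2 (-0.58). The count was 2491 or 2977 without olaparib replicate 1 or 3, where the lone array left was assumed to vary like the other groups.

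NR in atm-1 worms at day 10 (3 arrays against 3) raised cror-1 4.39-fold (log2 2.13 ± 0.16, adjusted p = 9.58e-12), the lipase lipl-2 3.17-fold (log2 1.66 ± 0.09) and the flavin monooxygenase fmo-2 2.15-fold (log2 1.1 ± 0.12). Pharynx genes rose: of 17 genes 10 rose, 1 fell and 6 did not pass (10 and 1 over the list alone, adjusted p = 2.56e-06, or 0.224 with an estimated correlation). Members included the troponin tnc-2 at 1.17 ± 0.09. tnt-4 (log2 1.64 ± 0.16) and acdh-1 (1.55 ± 0.21) rose too. The superoxide dismutase sod-3 was at 0.31 ± 0.09 (adjusted p = 0.00885), a call that ended without untreated replicate 1 (0.24) or 2 (0.25) or NR replicate 1 (0.27). F-box genes fell (of 345 genes 18 rose, 158 fell and 169 did not pass, 20 and 169 over the list alone, adjusted p = 6.09e-11, or 0.347 with an estimated correlation, fbxb-27 -1.41 ± 0.17). So did cuticle genes (10 rose, 53 fell and 122 did not pass, 11 and 55 over the list alone, adjusted p = 0.00628, or 0.475 with an estimated correlation, the collagen col-94 -2.25 ± 0.11). egl-1 fell (log2 -0.53 ± 0.11, adjusted p = 0.000393) and pink-1 did not pass (log2 0.08 ± 0.08, adjusted p = 0.561).

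In all, 5057 genes passed the threshold, 2129 higher and 2928 lower. 19 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 16 passed in the same direction with the slide as a term, the 3 lists named among them (adjusted p from 9.85e-07 to 0.0255). The count was 4754 with the slide as a term. The call held for cror-1 at 2.4, lipl-2 at 1.55, fmo-2 at 1.3, tnt-4 at 1.77, tnc-2 at 1.22, acdh-1 at 1.44, sod-3 at 0.40, fbxb-27 at -1.37 and col-94 at -2.37, and was lost for egl-1 at -0.28. The count was 3299 without untreated replicate 2 and 1063 with only these 6 arrays in the fit, where sod-3 and egl-1 lost their calls. Untreated replicate 3 lay beside the treated arrays, and without it 6054 genes passed here, 5282 for SRT1720 and 6621 for olaparib in atm-1 worms at day 10.

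SRT1720 in atm-1 worms at day 10 (3 arrays against 3) raised several genes. cror-1 (C01G12.5, chromosome II from 14586450 to 14586509) rose 11-fold (log2 3.46 ± 0.16, adjusted p = 4.19e-17), cyp-35B3 8.89-fold (log2 3.15 ± 0.10), cyp-35B2 8.32-fold (log2 3.06 ± 0.10), and the P-glycoproteins pgp-13 4.54-fold (log2 2.18 ± 0.11) and pgp-14 3.41-fold (log2 1.77 ± 0.16). Of the 74 cytochrome P450 genes, 30 rose, 2 fell and 42 did not pass (30 and 2 over the list alone, adjusted p = 5.87e-09, or 0.154 with an estimated correlation), and of the 43 glutathione S-transferase genes, 17 rose, 0 fell and 26 did not pass (23 and 0 over the list alone, adjusted p = 7.71e-09, or 0.211 with an estimated correlation). Members included gst-41 at 1.46 ± 0.09. sod-3 (log2 0.66 ± 0.09, adjusted p = 1.34e-06), mtl-1 (log2 1.33 ± 0.13) and fmo-2 (log2 1.27 ± 0.12) rose. Pharynx genes rose (of 17 genes 11 rose, 0 fell and 6 did not pass, 12 and 0 over the list alone, adjusted p = 9.97e-09, or 0.154 with an estimated correlation). Members included tnc-2 at 1.44 ± 0.09. For neuropeptides 51 rose, 2 fell and 50 did not pass (57 and 2 over the list alone, adjusted p = 2.55e-10, or 0.408 with an estimated correlation). Members included flp-13 at 0.98 ± 0.16. The atm-1 probe was lower with the compound (log2 -0.68 ± 0.16, adjusted p = 0.00173).

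In all, 4275 genes passed the threshold, 2531 higher and 1744 lower. 13 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 10 passed in the same direction with the slide as a term, the 4 lists named among them (adjusted p from 7.24e-12 to 0.0002). The count was 3220 with the slide as a term, and all 12 genes named here kept their call, among them cror-1 at 3.94, cyp-35B3 at 3.48, cyp-35B2 at 3.23, pgp-13 at 1.98, gst-41 at 1.41, sod-3 at 0.83, tnc-2 at 1.51, flp-13 at 1.14 and atm-1 at -0.93. The count was 2846 or 2510 without untreated replicate 1 or 2, and 300 with only these 6 arrays in the fit, where atm-1, sod-3 and flp-13 lost their calls.

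Olaparib in atm-1 worms at day 10 (3 arrays against 3) raised the lipase lips-11 8.81-fold (log2 3.14 ± 0.19, adjusted p = 2.89e-14), pgp-14 4.27-fold (log2 2.09 ± 0.16) and cyp-35B3 3.73-fold (log2 1.9 ± 0.10). Pharynx genes rose (of 17 genes 11 rose, 2 fell and 4 did not pass, 11 and 2 over the list alone, adjusted p = 4.03e-06, or 0.343 with an estimated correlation). Members included tnc-2 at 1.39 ± 0.09 and phat-6 at 1.4 ± 0.14. In the cytosolic heat shock list 10 rose, 0 fell and 16 did not pass (11 and 1 over the list alone, adjusted p = 0.00527, or 0.343 with an estimated correlation). Members included hsp-12.3 at 1.23 ± 0.08, and the endoplasmic reticulum chaperone hsp-4 rose (log2 0.52 ± 0.07). The desaturase fat-7 fell (log2 -1.2 ± 0.11). The parkin homolog pdr-1 fell (log2 -0.45 ± 0.08, adjusted p = 3.56e-05), egl-1 rose (log2 0.45 ± 0.11, adjusted p = 0.00154) and pink-1 did not pass (log2 -0.05 ± 0.08, adjusted p = 0.69). sod-3 was near the threshold (log2 0.24 ± 0.09, adjusted p = 0.0363), and its call ended without untreated replicate 1 (0.17) or 2 (0.18) or olaparib replicate 1 (0.21) or 3 (0.24). In all, 6175 genes passed the threshold, 2832 higher and 3343 lower, against 3244 and 3150 under normexp with quantile normalization and 1140 and 1105 with the slide as a term. 20 of 43 lists moved as a group, 0 with an estimated correlation. Of those lists, 12 passed in the same direction with the slide as a term, both lists above among them (adjusted p = 0.000346 and 0.00315), and 1 list passed in the opposite direction. The count was 2245 with the slide as a term. The call held for lips-11 at 3.08, pgp-14 at 1.81, cyp-35B3 at 2.28, tnc-2 at 1.45, phat-6 at 1.38, hsp-12.3 at 1.39, fat-7 at -1.4 and egl-1 at 0.79. It was lost for hsp-4 (0.46), pdr-1 (-0.06) and sod-3 (0.47). With only these 6 arrays in the fit sod-3 and egl-1 lost their calls, and with the slide as a random block sod-3 did.

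The interactions at day 10 asked again whether the compounds acted differently in both genotypes. For NR the genes of oxidative phosphorylation (27 of 57 negative, none positive, 1 and 29 over the list alone, adjusted p = 2.21e-09, or 0.0986 with an estimated correlation) and of the proteasome (18 of 34 negative, none positive, 0 and 22 over the list alone, adjusted p = 2.02e-08, or 0.0986 with an estimated correlation) had lower terms in atm-1 worms, and pgp-14 (log2 1.55 ± 0.22, adjusted p = 7.12e-06) and tnt-4 (log2 1.5 ± 0.22, adjusted p = 1.32e-05) higher ones (1.42 and 1.7 with the slide as a term, still called). In all, 3460 genes passed the threshold, 1607 higher and 1853 lower. For SRT1720 3584 genes passed, with cror-1 (log2 1.86 ± 0.22) and the pharynx factor ceh-22 (log2 1.72 ± 0.27) positive, the lipase lipl-3 (log2 -1.88 ± 0.16) negative (2.52, 1.33 and -1.85 with the slide as a term, still called) and neuropeptides mostly positive where they passed (40 positive, 2 negative and 61 not past the threshold, 47 and 3 over the list alone, adjusted p = 3.73e-08, or 0.419 with an estimated correlation). For olaparib 4925 genes passed, with lips-11 (log2 2.88 ± 0.28) and nlp-23 (log2 2.06 ± 0.31) positive, col-94 (log2 -2.19 ± 0.17) negative (2.49, 2.83 and -2.32 with the slide as a term, still called) and cytochrome P450 genes mostly positive where they passed (35 positive, 3 negative and 36 not past the threshold, 38 and 3 over the list alone, adjusted p = 2.71e-08, or 0.15 with an estimated correlation). The joint test over the 3 compounds gave 6787 genes, and 5054 with the slide as a term.

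The effects of a compound in both genotypes were also set side by side across genes, which are not independent replicates. At day 1 the correlation of the wild type with the atm-1 effect was 0.0348 for NR, 0.195 for SRT1720 and -0.133 for olaparib, and at day 10 it was 0.346, 0.181 and 0.224. In 100 simulations of unchanged groups made from the residuals of the arrays, a correlation as far from 0 came up 82, 21 and 38 times for day 1 and 5, 26 and 11 times for day 10. The covariance was 0.00271, 0.0262 and -0.014 at day 1 and 0.0511, 0.0228 and 0.0397 at day 10, against -0.00102 with an SD of 0.0089 in those simulations (-0.00134 and 0.0092 with a group of 2 arrays). Of the genes past the threshold in both genotypes at day 1, 15 were higher in both, 16 lower in both and 5 opposite for NR, 101, 788 and 129 for SRT1720, and 27, 120 and 322 for olaparib. At day 10 these numbers were 583, 926 and 462, then 341, 281 and 415, and 553, 783 and 730. Independent changes would have given 5.12, 360 and 142 opposite genes at day 1 and 713, 438 and 848 at day 10. With the slide as a term the olaparib value at day 1 turned to 0.0392, and those of day 10 fell to 0.221, 0.0832 and 0.106. At day 1 the olaparib value also turned with no filter (0.0627), the SRT1720 value was 0.31 under normexp with quantile normalization, and the NR value ran from -0.0492 (without atm-1 NR replicate 1) to 0.115 with single arrays left out.

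The last question was whether a compound moved genes of untreated atm-1 worms back toward the wild type. Genes past the threshold for genotype and for the compound in atm-1 worms went against the genotype difference or along with it. At day 1 there were 317 opposite and 264 alike for NR, 2135 and 941 for SRT1720 and 675 and 224 for olaparib. At day 10 they were 1068 and 512, 1024 and 306, and 1391 and 577 in that order. Independent changes would have given 205 to 1170 opposite genes at day 1 and 533 to 747 at day 10. Both comparisons used the same untreated atm-1 arrays, whose error alone gives opposite changes: in 100 simulations with no compound effect the highest number opposite was 41, 4 and 7 at day 1 and 175, 677 and 1169 at day 10. The covariance of both effects across genes was -0.0213, -0.0603 and -0.058 at day 1 and -0.0264, -0.0225 and -0.039 at day 10 for NR, SRT1720 and olaparib, against -0.029 with an SD of 0.015 (-0.0299 and 0.013 for NR at day 1) in simulations of unchanged groups that share untreated arrays. The values of day 10 and that of NR at day 1 lay within 1 SD of the simulated mean. At day 1 SRT1720 and olaparib lay about 2 SD below it. The untreated atm-1 arrays' own error gave -0.0162 at day 1 and -0.024 at day 10. Whether shared arrays account for day 10 stays open, since its opposite counts exceeded every simulation. The opposite genes numbered, with the slide as a term, 82, 144 and 25 at day 1, and 527 for SRT1720 and 468 for olaparib at day 10. Without untreated atm-1 replicate 2 the count was 152 (NR, day 1), 427 (olaparib, day 1) and 627 (SRT1720, day 10).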

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

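The tests of untreated atm-1 replicate 3 at day 10, and that of brightness as the whole cause, were chosen after seeing the data, and the other tests of this part before.

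Each result here was tested as an interaction. The change with age differed between genotypes in 6381 genes. The effect of a compound differed in 412 genes for NR, 2239 for SRT1720 and 3150 for olaparib at day 1, and in 3460, 3584 and 4925 at day 10. Joint tests over the 3 compounds gave 5063 genes at day 1 and 6787 at day 10. With genotypes redrawn within each day, only the real split of 100 gave as many genes as the age interaction (highest other 5891). Splits can keep the day 1 genotype difference, so they do not test the interaction.

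The first pattern weighed was the genotype difference in untreated worms at day 1 (9193 genes). Against the slides of the untreated arrays as the whole cause, the genotype differences of untreated worms correlated across genes with those measured on the other 2 pairs of slides at day 1, at 0.672 (slides with NR and SRT1720) and 0.635 (spread 0.12, slides with SRT1720 and olaparib), past a limit of 0.5 set beforehand. Each slide held 1 genotype, so a difference common to all slides of a genotype is not excluded by this. Untreated atm-1 arrays were brighter (75th percentile 4539 to 5458) than untreated wild type arrays (2751 to 3258). Against brightness as the whole cause, the differences among olaparib-treated worms, whose arrays overlapped in brightness, had a slope of 0.552 (spread 0.083) on those of untreated worms over the genes past the threshold. How much of the size of the differences came from brightness cannot be told apart from genotype, since the slope over all genes was 0.507 (spread 0.087) against a limit of 0.5 set beforehand. A candidate explanation is that atm-1 worms were further advanced toward the day 10 state: the genotype difference among olaparib-treated worms correlated with the wild type change with age at 0.443 (spread 0.062) across genes, with no array shared. A difference in growth rate or stage between the strains stays open and was not tested apart from this.

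The second pattern weighed was untreated atm-1 replicate 3 at day 10, which lay with the treated arrays. A swap with a treated array needs a partner out of place, and 0 of the 9 treated atm-1 arrays lay nearer to untreated replicates 1 and 2 than to the arrays of the other compounds. A slide difference is argued against, since all 3 untreated arrays shared 1 slide. Whether it was an array of worms given a compound cannot be told apart: its distance to the nearest compound (NR) was 0.374, within the 0.273 to 0.533 of treated arrays from their own compound, and its distance to untreated replicates 1 and 2 was 0.378. No biological explanation was tested.

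Other splits of the 6 arrays of a comparison number 10 with the real one, too few for a share under 0.05, and in each comparison 1 of the 10, the real split, gave as many genes. The real value and the highest other were 9193 and 1 for genotype at day 1, 4374 and 1 at day 10, 13993 and 1 for age in the wild type, and 14168 and 9 in atm-1 worms. For compounds at day 1 they were 196 and 1 (NR, wild type), 2832 and 14 (SRT1720, wild type), 3419 and 29 (olaparib, wild type), 4552 and 2 (SRT1720, atm-1) and 1470 and 4 (olaparib, atm-1). At day 10 they were 5221 and 0 (NR, wild type), 3535 and 290 (SRT1720, wild type), 5057 and 2424 (NR, atm-1), 4275 and 1850 (SRT1720, atm-1) and 6175 and 75 (olaparib, atm-1). The 2424 and 1850 genes came from splits with untreated replicate 3 among the treated arrays, which points to a structure of the samples.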

How the results depend on the processing

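Leaving out the dim arrays, the slide as a random block for compounds, and array weights were chosen after seeing the data, and the other alternatives before. Where a number moved, the cause was not tested unless stated.

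Of the 19 counts of genes, 19 stayed within 1.5 times under normexp with quantile normalization, quantile normalization, no filter, the stricter filter, either replicate block and the slide as a random block. Fewer genes passed, by more than that, in 10 counts with the slide as a term, in 15 with the values of the authors' table, in 8 with only the groups compared (1 rose) and in 2 without the dim arrays. With array weights 9 counts rose.

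The slide as a term ended part of the list calls. Of the lists that moved as a group, 12 of 19 (NR), 15 of 23 (SRT1720) and 10 of 24 (olaparib) held in the wild type at day 1, and 14 of 17, 7 of 13 and 6 of 13 in atm-1 worms. At day 10 it was 12 of 18, 11 of 18 and 10 of 23 in the wild type and 16 of 19, 10 of 13 and 12 of 20 in atm-1 worms. Of the rest, 1 list turned for SRT1720 and 1 for olaparib in the wild type and 1 for olaparib in atm-1 worms. The counts of genes were 20, 14 and 17 in the wild type and 339, 347 and 79 in atm-1 worms at day 1, 532 (SRT1720) and 1257 (olaparib) in the wild type and 2245 (olaparib) in atm-1 worms at day 10, and 1136 in the joint interaction test at day 1. Fewer arrays carry the effect by construction. Genes whose change with a compound was opposite to the genotype difference numbered 82, 144 and 25 at day 1, and 527 (SRT1720) and 468 (olaparib) at day 10. Correlations of an effect across genotypes became 0.0392 (olaparib, day 1, turned), 0.221, 0.0832 and 0.106 (day 10).

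With the value table, on a scale of scores, the counts were 2371 (genotype, day 10), 35, 848 and 1628 (NR, SRT1720 and olaparib, wild type, day 1), 154, 2322 and 761 (atm-1, day 1), 1859 (NR) and 2279 (olaparib) in the wild type and 2850, 2281 and 3993 in atm-1 worms at day 10, 4136 (age by genotype), and 1809 and 3687 (joint interaction tests). Opposite genes numbered 67, 969 and 329 at day 1 and 498, 401 and 674 at day 10.

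A fit of only the groups compared, which leaves fewer residual degrees of freedom, gave counts of 1695 (genotype, day 10), 31, 1622 and 1118 (NR, SRT1720 and olaparib, wild type, day 1), 2623 (NR, atm-1, day 1), 35 (SRT1720, wild type, day 10), 1063 (NR) and 300 (SRT1720) in atm-1 worms at day 10, and 4459 (joint test, day 10). Opposite genes numbered 1177 (NR, day 1) and 270, 101 and 612 (day 10).

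With array weights they were 4375 (NR) and 5088 (SRT1720) in the wild type and 4651, 9503 and 4279 in atm-1 worms at day 1, 7894 (NR) and 8822 (olaparib) in the wild type and 7778 (NR) in atm-1 worms at day 10, and 9907 (joint test, day 1). Opposite genes numbered 1801, 4321 and 2180 at day 1 and 1861 for NR at day 10. With the 2 excluded arrays NR in atm-1 worms at day 1 gave 1949 genes and 573 opposite ones. Without the dim arrays olaparib in atm-1 worms at day 1 gave 949 and SRT1720 in the wild type at day 10 gave 1730. The correlation across genotypes was 0.31 for SRT1720 at day 1 under normexp and turned to 0.0627 for olaparib at day 1 with no filter.

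A further limit of 2-fold, stricter by construction, left 985 and 317 genes for genotype, 7306 and 7184 for age, 1211 for age by genotype, 16, 113 and 165 (wild type) and 51, 453 and 128 (atm-1) for the compounds at day 1, and 326, 132 and 317 (wild type) and 315, 276 and 603 (atm-1) at day 10.

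Leaving out each array in turn gave ranges of 65 to 153 (NR), 1187 to 2656 (SRT1720) and 1898 to 3416 (olaparib) genes in the wild type at day 1. In atm-1 worms they were 194 to 667 for NR and 872 to 1418 for olaparib. At day 10 they were 1677 to 3732 (SRT1720) and 2491 to 5192 (olaparib) in the wild type and 3299 to 6054 (NR) and 2510 to 5282 (SRT1720) in atm-1 worms, the highest of each pair in atm-1 worms without untreated replicate 3. The lowest values came without untreated replicate 2 (NR, wild type, day 1), untreated replicate 3 (SRT1720 and olaparib, wild type, day 1), NR replicate 1 or olaparib replicate 3 (atm-1, day 1), SRT1720 replicate 3 or olaparib replicate 1 (wild type, day 10) and untreated replicate 2 (atm-1, day 10). The other counts stayed within 1.5 times. Opposite genes ranged from 75 to 302 (NR, day 1, lowest without NR replicate 2), 422 to 617 (olaparib, day 1, lowest without olaparib replicate 3) and 627 to 1100 (SRT1720, day 10, lowest without untreated replicate 2). The correlation of the NR effect across genotypes at day 1 ranged from -0.0492 (without atm-1 NR replicate 1) to 0.115.

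Of the 182 gene values named, 159 kept their direction and side of the threshold with the slide as a term (23 lost the call), 167 with only the groups compared (14 lost, 1 gained), 177 with the value table (5 lost), 180 with the slide as a random block (2 lost), and all but at most 1 under each other alternative. Leaving out 1 array did so for 1188 of 1202 values (11 lost, 3 gained). Of 76 list results, 27 held and 49 lost the call with an estimated correlation, 73 held under normexp (2 lost, and the list of cytosolic ribosomal proteins in the genotype comparison at day 1 turned, adjusted p = 0.939), 74 under quantile normalization, all 44 tested with the slide as a term, and 75 or 76 under each other alternative. These genes and lists were picked in part for holding, so the shares of all called lists given above describe the lists better. Lists were not run with the slide as a block for genotype and age, since camera takes no random block. Signal over background limited the dim arrays, on which 53.3% and 64.6% of spots were well above background, against a median of 73.9%.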

Other observations

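The values here carry no test. At day 10 the median log2 difference (atm-1 minus wild type) of 17 pharynx genes was 0.01 in untreated worms and 0.38, 0.52 and 0.55 with NR, SRT1720 and olaparib, that of 47 muscle genes was 0.06 against 0.37, 0.34 and 0.26, and that of 62 neuron genes was 0.03 against 0.24, 0.20 and 0.28. It was 0.18 against 0.29, 0.26 and 0.29 for the gonadal sheath and spermatheca, 0.01 against -0.04, -0.09 and -0.25 for the germline, 0.03 against -0.05, -0.12 and -0.43 for oocytes, 0.04 against -0.05, -0.13 and -0.12 for the cuticle, and -0.03 against 0.21, 0.03 and 0.07 for the intestine. Proteasome genes had a median of 0.14 in untreated worms and of -0.19, 0.03 and -0.19 with the compounds, and cytochrome P450 genes of -0.12 against 0.16, 0.17 and 0.32. Sperm genes were higher in atm-1 worms in each of the 4 arms (0.43, 0.49, 0.72 and 0.40).

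At day 1 the genotype difference kept its sign in each of the 4 arms for DNA repair and replication genes (0.38 untreated, then 0.36, 0.22 and 0.36), germline genes (0.41, 0.38, 0.24 and 0.26), mitophagy and autophagy genes (0.14, 0.16, 0.10 and 0.25) and cuticle genes (-0.62, -0.42, -0.33 and -0.50). Across genes, which are not independent replicates, the genotype difference of untreated worms correlated with that of worms given NR, SRT1720 and olaparib at 0.754, 0.578 and 0.563 at day 1 and at 0.444, 0.434 and 0.202 at day 10.

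Effects of different compounds within a genotype and day share their untreated arrays, which alone gave a mean correlation of 0.512 (0.488 with a group of 2 arrays) in 100 simulations. The values seen ran from 0.188 (NR with olaparib, wild type, day 1) to 0.649 (NR with olaparib, atm-1, day 10), and none reached the highest simulated value of 0.798 (0.803 with a group of 2). Their covariances, against 0.029 with an SD of 0.015 (0.0299 and 0.013 with a group of 2) in the simulations, lay more than 2 SD higher for the 6 pairs at day 10 (0.0727 to 0.109), for SRT1720 with olaparib in the wild type at day 1 (0.0654) and for NR with SRT1720 in atm-1 worms at day 1 (0.0783), but not for the other 4 pairs (0.0159 to 0.0435).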
